A study of Homo sapiens with 14 samples.

How the data were processed

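Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in HS-SY-II, a synovial sarcoma cell line, with an antibody to GLTSCR1, the subunit that marks the GBAF form of the BAF chromatin remodelling complex, and with an anti-HA antibody that recognises a tagged SS18::SSX fusion protein. Cells received vehicle (DMSO) or 100 nM of WA-68, a PROTAC that directs the GBAF subunit BRD9 to degradation. The 5 GLTSCR1 libraries came from DMSO and 12, 24, 48 and 96 h of WA-68, and the 4 fusion libraries from DMSO and 12, 24 and 48 h. The reads of the 5 input libraries were not analysed here. Each group held 1 library, so no test between conditions was made and no p-value is given. The labels give no time for DMSO, and 1 DMSO library per antibody was the reference for every later time. Time in culture therefore cannot be told apart from time of WA-68.

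The deposited files were peak lists, 1 per library, with positions on GRCh38 per the submitters' processing notes. Those notes name bcl2fastq, FastQC, Trim Galore, cutadapt, BWA, SAMtools, Picard, MACS2 and deepTools; their versions, order and settings are not given in the sources used here. Peaks were called for each library separately, per the peak names in the deposited files. For each peak the authors gave the fold enrichment of its summit over local background, a linear ratio, with −log10 p and −log10 q values from their peak caller. The lowest deposited −log10 q was 3.00 in all 9 lists. Fold values were used only to describe, rank or group peaks within their own list, since they depend on each library's depth and background. Read depth is unknown from peak lists, so a peak missing from a list was below the caller's threshold in that library, which does not show that the protein was absent.

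Entries with the same coordinates, which hold several summits of 1 region, were joined into 1 region that carried the values of its strongest summit. Regions on chromosomes 1 to 22, X and Y were kept. A DMSO peak counted as still called when a later peak of the same antibody overlapped it by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only; neighbouring peaks are not independent, and the intervals say nothing about variation between cultures. Chance overlap came from 100 random placements of the later peaks within their chromosomes. Positions were drawn evenly, without regard to gaps, mappability or open chromatin, so this chance level is a low bar. Differences between kinds of DMSO peaks were computed within deciles of DMSO fold and averaged over the peaks, with 95% intervals of the same kind of counting error. Regions wider than 5 kb were called wide.

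The gene table used here (GRCh38.p14) gives the span of each gene without strand, transcription start sites, exons or introns. The planned window around transcription start sites was therefore replaced, once this table had been seen, by the 1 kb on either side of both ends of each of 20033 protein-coding gene spans. Such gene-end windows include downstream ends and miss internal promoters. A gene counted as bound when any peak overlapped either window; the fold given for it is that of the strongest summit of the strongest overlapping region, which can lie outside the window. Neighbours in gene clusters can share a region and are then not independent.

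Before the data were examined, 13 gene lists with 333 genes were fixed from general knowledge of the field, along with the comparisons, the alternatives in processing and the rule for named genes. All 333 symbols matched the gene table. The share of a list that was bound was placed among 10000 random lists of the same size, and the share of its DMSO-bound genes still bound was placed among 10000 random lists matched on decile of DMSO fold; both percentiles describe these libraries and test nothing between conditions. For each antibody the rule named the 8 genes with the highest DMSO fold among those bound at every later time, the 8 highest among those bound at no later time, the 8 genes without a DMSO peak and with a peak at every later time that had the lowest mean percentile rank, up to 4 members of each list by DMSO fold, and BRD9, BICRA, SS18 and the SSX genes in any case. Away from gene ends it named the 3 strongest DMSO peaks called at every later time and the 3 strongest called at none. Other genes and regions named in the text were chosen after their values were seen, and this is said where they appear. A few genes that the rule names are not reported here.

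The alternatives were an overlap of at least 50% of the shorter peak, and summits within 250 bp. For the latter only the strongest summit of each region was compared. A region with several summits could therefore fail when a different one was strongest. Others were −log10 q of at least 5 in every list or in the reference list alone, and lists of equal length. The rest were merging of peaks within 500 bp, all contigs, and gene-end windows of 3 kb and 500 bp. Added after the data had been seen were a peak anywhere in the gene span, leaving out 1 later list at a time, and matching on quintiles of both fold and width. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap and matching steps were tested on a simulated list of 18037 peaks, the length of the GLTSCR1 DMSO list, with random positions, widths and folds. A kept share of 51.7% came back as 51.7% with 0 wrong calls. Those peaks were spaced apart and shifted by less than their width, so that result was fixed by design and checked the code only. A difference set at −15 points came back as −16.2 ± 1.40, and 5 of 100 draws without a difference fell outside their interval. Clustered or very wide regions were not simulated.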

Results

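BRD9 holds GBAF together with GLTSCR1, and SS18::SSX, the fusion oncoprotein of synovial sarcoma, enters BAF complexes through its SS18 part. The series followed where GLTSCR1 and the HA-tagged fusion were found on chromatin in HS-SY-II cells before and during exposure to the BRD9 degrader WA-68 (100 nM). The GLTSCR1 lists held 18037 regions in DMSO, 16021 at 12 h, 15330 at 24 h, 13677 at 48 h and 15611 at 96 h. They covered 16.8 Mb in DMSO and 11.1, 10.5, 8.55 and 10.3 Mb at the later times. The fusion lists held 24953 regions in DMSO, 28619 at 12 h, 24846 at 24 h and 26405 at 48 h, over 33.9, 36.4, 30.3 and 33.4 Mb. With 1 library per group there was no replicate error to set these differences against, and intervals below cover counting error only. All folds are the authors' summit enrichments within 1 list, so folds from different lists do not show a rise or fall in binding.

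The first comparison was of GLTSCR1 in treated and DMSO cells. Among genes with a GLTSCR1 peak at every time, the rule named those with the highest DMSO folds. CRIP2, a LIM-domain gene on chromosome 14, had a peak at 105479856 to 105482941 with a DMSO fold of 41.3, and JUND, which encodes an AP-1 transcription factor, had one on chromosome 19 at 18280905 to 18282707 with a fold of 39.2. The BET bromodomain gene BRD2 followed at 38.2, the transcription factor gene RFX1 at 38.1, and the histone genes H2AC8, H2BC8 and H3C6, which share 1 region of 14.8 kb on chromosome 6, at 35.1. LOC124909494, which lies in a region of 81.7 kb with ZIC1 and ZIC4 on chromosome 3, had a fold of 33.7.

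Of the GLTSCR1 DMSO peaks, 55.8% (95% interval 55.1 to 56.6) were still called at 12 h, 47.6% (46.9 to 48.4) at 24 h, 43.2% (42.4 to 43.9) at 48 h and 48.6% (47.9 to 49.3) at 96 h. No random placement exceeded 1.12% at any of these times, which is a low bar since placements ignored gaps and open chromatin. A total of 4814 peaks (26.7%) were called at every later time and 4690 (26.0%) at none. Retention was highest in the highest decile of DMSO fold, with 93.2% kept at 12 h and 82.8% at 48 h. It was not ordered among weaker peaks: the lowest decile had 42.2% and 36.3%, and the next but one 40.0% and 29.7%. Strongest summits within 250 bp, in place of overlapping peaks, gave 39.4% at 12 h and 30.4% at 48 h.

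**Figure D1:**
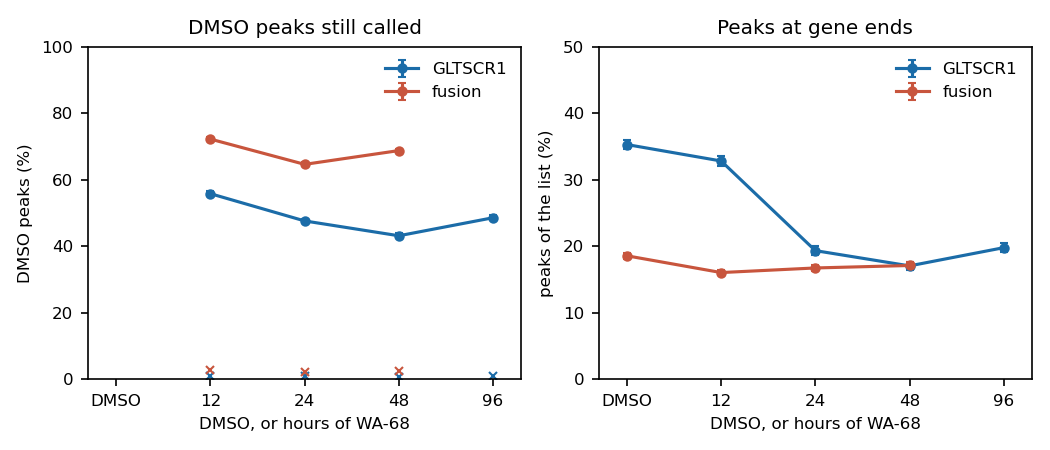
Left, share of DMSO peaks still called at each time of WA-68, with 95% exact intervals for counting error and crosses for chance overlap. Right, share of each list's peaks within 1 kb of a gene end; 1 library per point. GLTSCR1 retention lies between 43.2% and 55.8%, below that of the fusion, and the GLTSCR1 share at gene ends is 32.8% at 12 h and 19.3% at 24 h.

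Genes whose ends lost every GLTSCR1 call were led by CDKN2C, a CDK inhibitor gene, with a DMSO fold of 22.2, CDC25B, a CDK-activating phosphatase gene, with 16.4, and the transcription factor gene EBF3, with 11.2. In all 4 later lists a peak outside the 1 kb window nonetheless overlapped the DMSO peaks of these 3 genes. The same held for CISD1 (10.2) and TMEM47 (9.74). These 5 of the 8 thus lost their calls within the window but not over the whole DMSO peak. An overlap of 1 bp was enough here, so a loss at the gene end itself stays possible. For the other 3 genes the peak itself was in no later list: TNKS1BP1 on chromosome 11 at 57325087 to 57325819 (fold 10.6), ATP13A1 on chromosome 19 at 19663103 to 19663989 (10.6) and TAX1BP1, an autophagy receptor gene, on chromosome 7 at 27739602 to 27740399 (10.3). Among all 1360 genes bound in DMSO and at no later time, the strongest DMSO peak was overlapped by a later peak in 48 (3.53%). Against these stood 1260 genes bound in DMSO and at every later time, out of 6233 bound in DMSO. With a peak anywhere in the gene span, 2325 genes were bound in DMSO and at every later time.

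Only 45 genes had no GLTSCR1 peak at their ends in DMSO and 1 at every later time. NCBP2L on the X chromosome had folds of 21.0, 14.5, 23.4 and 25.0 at 12, 24, 48 and 96 h. ZNF778, FAM98C, SLITRK3, GLP1R, LMO2, ATP9B and GLRX3 followed. At LMO2, which encodes a LIM-domain transcriptional adaptor, the folds were 7.02, 9.10, 6.75 and 8.46. None of the 8 peaks at 12 h overlapped a DMSO peak. SLITRK3, GLP1R, LMO2 and ATP9B carried a fusion peak in all 4 fusion lists.

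Away from gene ends, the strongest GLTSCR1 peak of the DMSO list (fold 57.4), which was called at every time, lay on chromosome 17 at 80491680 to 80492866, 15.1 kb from NPTX1, outside protein-coding spans. Next among peaks called at every time came a region of 54.4 kb inside the span of DNM3 on chromosome 1 at 172134834 to 172189256 (40.4) and a peak 18.7 kb from FOS on chromosome 14 at 75258056 to 75260154 (39.9). The strongest ones called at no later time had folds of 11.7 near YBX2 (chromosome 17, 7296090 to 7296697), 11.2 near EAPP (chromosome 14, 34545761 to 34546472) and 10.3 within C1QTNF8 (chromosome 16, 1089467 to 1090916).

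The second comparison was of the fusion in treated and DMSO cells. Among genes with a fusion peak at every time, the rule named those with the highest DMSO folds. These were ALDH1A2, which encodes a retinoic acid-producing enzyme, with a fold of 19.8 (chromosome 15, 58042786 to 58067688), HMGCLL1 with 18.4, BMP3, a bone morphogenetic protein gene, with 17.8, THSD7A with 16.8, the neighbours ISL2, LOC124903532 and SCAPER, which share 1 region, with 16.7, and the cannabinoid receptor gene CNR1 with 16.6. BMP3 had no GLTSCR1 peak at its ends in any list.

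Fusion DMSO peaks were still called in 72.3% of cases (71.7 to 72.8) at 12 h and 64.7% (64.1 to 65.3) at 24 h. At 48 h the share was 68.8% (68.2 to 69.4). Random placement, the same low bar, gave at most 3.04% at any time. A total of 12671 (50.8%) were called at every later time and 3579 (14.3%) at none (5498 without the 12 h list). In the highest decile of DMSO fold at least 99.4% were kept at each time. With strongest summits within 250 bp the shares were 35.9%, 33.9% and 35.5%. A region with several summits can fail here because a different one became strongest. Over the times both antibodies share, 29.1% of GLTSCR1 DMSO peaks were called at 12, 24 and 48 h.

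**Figure D2:**
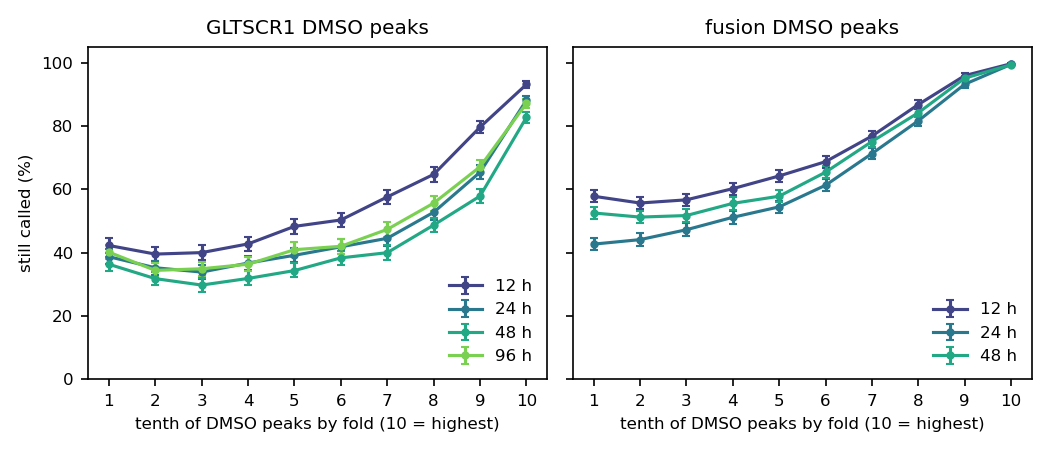
Share of DMSO peaks still called by decile of the authors' DMSO fold, for GLTSCR1 at 4 later times and the fusion at 3, with 95% exact intervals for counting error. In the highest decile GLTSCR1 retention is 82.8% to 93.2% and fusion retention at least 99.4%.

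The genes whose fusion calls were absent at every later time had top DMSO folds below those of the kept genes named above. These genes still had top folds in decile 9 of 10 of the fusion DMSO list (6.38 to 8.12). FKBP9 led them with a DMSO fold of 6.84, followed by the neighbours ADPRS and TEKT2, which share 1 peak (6.72), SLC8A2 (6.71), NEBL (6.59), the lysosomal membrane gene LAMP1 (6.53), RRAGB (6.51) and the transketolase gene TKT (6.51). None of their DMSO peaks was overlapped later. NEBL kept a GLTSCR1 peak in all 5 GLTSCR1 lists. In all, 748 of 3872 genes bound in DMSO were bound at no later time and 1787 at every later time.

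A further 181 genes had a fusion peak at their ends at every later time and none in DMSO. Those ranked highest included FGF4, TNFRSF14, COL9A1, PPP2R2C, FOXB2 and TMEM250. Among all 181 genes, the strongest 12 h peak overlapped a DMSO peak outside the window in 13 (7.18%). At TNFRSF14, COL9A1, FOXB2 and TMEM250 the peak at 12 h did so. It overlapped none at FGF4, a growth factor gene on chromosome 11, with folds of 5.29, 6.94 and 6.35, or at PPP2R2C on chromosome 4, with 6.92, 5.60 and 5.42. The strongest fusion peaks away from gene ends that were called at every time lay within ADAP1 on chromosome 7 (934209 to 937999, fold 42.5), within MCF2L on chromosome 13 (113062627 to 113071308, 34.8) and 14.3 kb from FAM53A on chromosome 4 (1530360 to 1559735, 34.7). The strongest called at no later time lay within HIC2 (chromosome 22, 21419920 to 21420581, 8.52), CHD3 (chromosome 17, 7886561 to 7887622, 8.32) and ZNF423 (chromosome 16, 49698224 to 49699907, 7.68); GLTSCR1 was called over the CHD3 and ZNF423 peaks in all 5 GLTSCR1 lists.

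The third comparison was of GLTSCR1 and the fusion at the same time. TWIST1, HOXC10, HOXC11, FOXF1 and KLF6 carried both proteins at their ends in DMSO and at 12, 24 and 48 h. RFX1, SMARCE1 and ARID2 carried GLTSCR1 at all 5 times; SMARCE1 and ARID2 had a fusion peak in DMSO alone, and RFX1 in DMSO and at 48 h. A fusion peak overlapped 59.3% (58.6 to 60.0) of GLTSCR1 peaks in DMSO, 55.2% (54.4 to 55.9) at 12 h, 54.1% (53.4 to 54.9) at 24 h and 66.7% (66.0 to 67.5) at 48 h. The reverse share, of fusion peaks with GLTSCR1, was 36.2% in DMSO and 24.2%, 26.6% and 25.3% later. At gene ends 57.1% of fusion peaks overlapped GLTSCR1 in DMSO, 39.1% at 12 h, 28.4% at 24 h and 31.7% at 48 h. Of GLTSCR1 peaks at gene ends, 39.8% overlapped the fusion in DMSO and 32.3%, 35.5% and 58.7% at 12, 24 and 48 h. Random placement, the same low bar, gave at most 2.35%. The GLTSCR1 share with summits within 250 bp was 22.5% in DMSO, with 22.4%, 22.5% and 26.6% later.

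The fourth comparison asked which DMSO peaks persisted. Gene ends held fewer of the GLTSCR1 calls from 24 h on: they had 35.3% of its peaks in DMSO, 32.8% at 12 h, 19.3% at 24 h, 17.0% at 48 h (25.8% with windows of 3 kb) and 19.8% at 96 h. The number of genes bound at an end was 6233, 5321, 2940, 2230 and 3037; anywhere in the gene span the last 3 counts were 4751, 3653 and 4690. At like DMSO fold, gene-end peaks were kept 4.89 points more often than others at 12 h (3.44 to 6.34), but the difference was −19.9 points at 24 h (−21.3 to −18.5), −26.3 at 48 h (−27.6 to −25.0) and −21.1 at 96 h (−22.4 to −19.7). With windows of 3 kb the 12 h value was 1.62 (0.22 to 3.01), and with summits within 250 bp the 24 h value was −12.8. For the fusion it was −11.9 at 12 h (−13.2 to −10.5; −5.69 with such summits), −3.95 at 24 h (−5.33 to −2.57; −1.85 with windows of 3 kb) and −5.71 at 48 h (−7.08 to −4.34), and fusion peaks at gene ends were 18.6% of the list in DMSO and 16.0%, 16.7% and 17.1% later.

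GLTSCR1 peaks that overlapped a fusion peak in DMSO were called more often than others from 24 h on. At like fold the difference was 1.35 points at 12 h (−0.044 to 2.74), 15.4 at 24 h (14.0 to 16.8), 27.2 at 48 h (25.9 to 28.6) and 22.3 at 96 h (20.9 to 23.7). Matching on width as well gave −4.82 at 12 h, 9.54 at 24 h, 22.4 at 48 h and 17.3 at 96 h, and summits within 250 bp gave 5.17, 8.77, 11.8 and 10.2. At gene ends, 31.9% of GLTSCR1 peaks with the fusion and 9.23% of those without were called at every later time; elsewhere the shares were 36.1% and 20.0%. Among genes with GLTSCR1 at an end in DMSO, 847 of 2591 with the fusion kept it at every time, against 413 of 3642 without. For fusion peaks called at every later time, those with GLTSCR1 differed from those without by 0.499 points at like fold (−0.647 to 1.64), by −7.49 once width was matched too and by 3.75 with summits within 250 bp.

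Genes linked to the fusion in synovial sarcoma were bound by both proteins in DMSO: all 20 of the list for GLTSCR1 and all 20 for the fusion. GLTSCR1 was at 17 of them at 12 h, 13 at 24 h, 15 at 48 h and 17 at 96 h, and the fusion at 18, 19 and 19. TWIST1, a mesenchymal transcription factor gene, was bound in all 9 lists, with GLTSCR1 folds of 15.1 in DMSO and 6.74 at 96 h. ZIC5, the anti-apoptotic gene BCL2 and FLRT2 had no GLTSCR1 peak at their ends at 24 h and had 1 at the other times. Their DMSO GLTSCR1 peaks were still overlapped by a GLTSCR1 peak in all 4 later lists. The absence at 24 h therefore applies to the gene-end window and not to the whole DMSO peak. The fusion was called at these genes in all 4 fusion lists. ZIC2, MNX1 and LMX1B had fusion folds of 14.9, 14.3 and 10.9 in DMSO and were called by the fusion at every time. For GLTSCR1, 11 of 20 were bound throughout, at the 95.5th percentile of fold-matched random lists (46.6th at 12 h, 63.7th at 24 h, 99.3rd at 48 h and 98.6th at 96 h), and for the fusion 18 of 20, at the 98.0th.

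HOX genes, which set body-axis identity, were bound by the fusion in 36 of 39 cases in DMSO and 35, 35 and 36 later, and by GLTSCR1 in 25 and then 22, 23, 23 and 22. GLTSCR1 stayed at 19 of its 25 at every time, against a median of 44.0% in fold-matched random lists. At 12 h alone the list lay at the 40.9th percentile. Neighbouring HOX genes can share a region while random lists draw genes singly, so the 25 are not independent. Within the HOXC cluster on chromosome 12, HOXC4 had a GLTSCR1 fold of 22.6 in DMSO, and HOXC10 and HOXC11 shared a region of 28.1 kb with a fold of 16.8. HOXB6 on chromosome 17 had 14.5. The fusion was strongest in DMSO at HOXD13 (12.6), HOXA10 and HOXA9 (12.2, 1 shared region) and HOXD11 (11.7), all kept at every time. Of the 50 other developmental transcription factor genes the fusion was at 38, 36, 38 and 37, and GLTSCR1 at 24, 14, 16, 17 and 20; windows of 3 kb gave GLTSCR1 at 24 at 12 h and 27 at 48 h. Of the 24 DMSO genes, 14 kept GLTSCR1 at 12 h, at the 0.71st percentile of fold-matched random lists, and 16 at 48 h, at the 98.2nd. At PAX6 and GATA2, with fusion folds of 12.4 and 11.5, GLTSCR1 was called in DMSO alone. NKX2-2 had the highest DMSO fusion fold of this list (15.9). DLX1, FOXF1 and SIM1 kept GLTSCR1 throughout and MSX1 had it at its ends in DMSO and at 12 h. The MSX1 DMSO peak was still overlapped by a GLTSCR1 peak in all 4 later lists. The later absence therefore applies to the gene-end window and not to the whole DMSO peak.

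**Figure D3:**
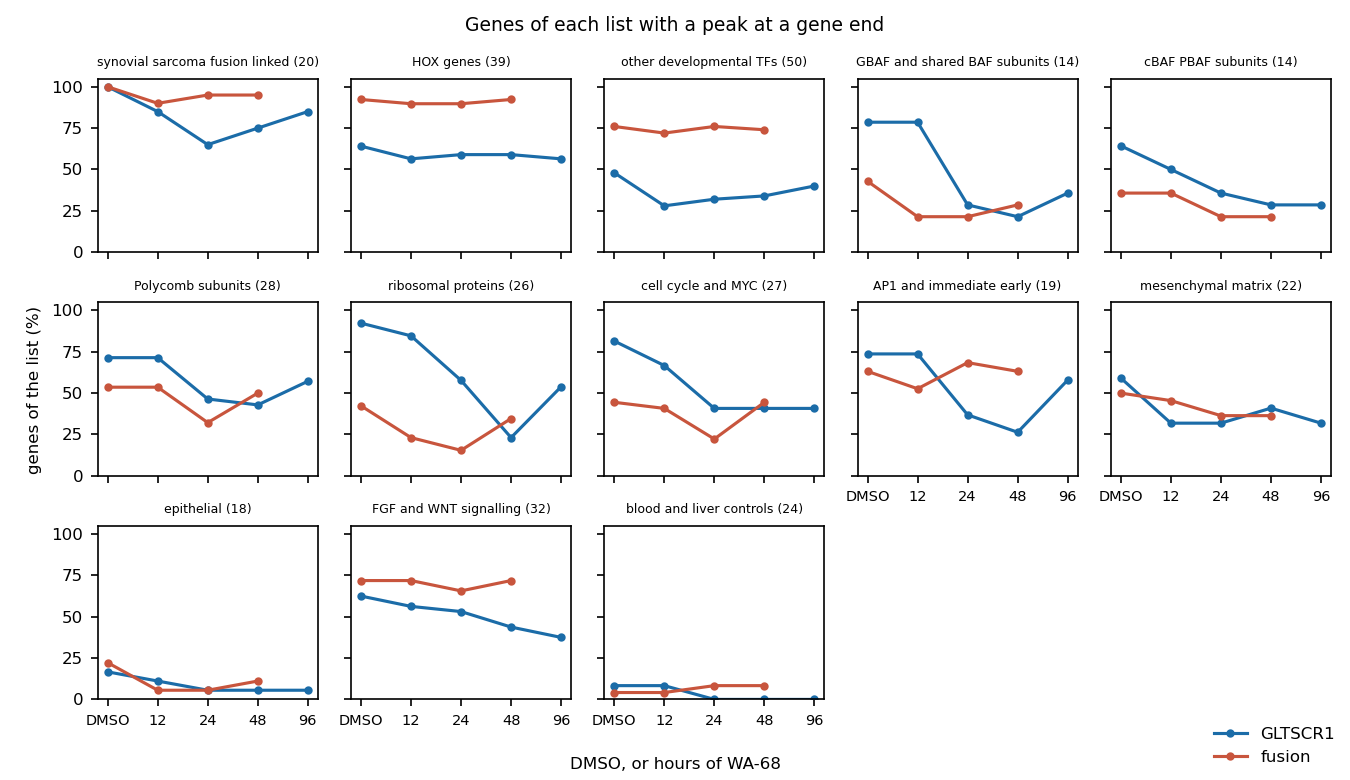
Share of each fixed gene list (number of members in brackets) with a GLTSCR1 or fusion peak within 1 kb of a gene end, in DMSO and at each time of WA-68; 1 library per point. The fusion stays at 35 or 36 of 39 HOX genes, and GLTSCR1 goes from 24 of 26 ribosomal protein genes in DMSO to 6 at 48 h.

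Ribosomal protein genes had GLTSCR1 at 24 of 26 in DMSO, 22 at 12 h, 15 at 24 h, 6 at 48 h and 14 at 96 h. RPL13 (DMSO fold 10.6) was missing at 24 h, RPL19 at 48 h, and RPS23 at 48 and 96 h. Of the 24, 4 were kept throughout, at the 14.7th percentile of fold-matched random lists. Taken by time, the 15 kept at 24 h lay at the 95.4th percentile and the 6 kept at 48 h at the 8.2nd, so the list held no steady place. The fusion was at 11 of the 26 in DMSO and 6, 4 and 9 later, with RPS2 (7.51) kept and RPS14 called in DMSO alone; RPS9 was called in DMSO and at 12 h. Cell cycle and MYC genes had GLTSCR1 at 22 of 27 in DMSO, 18 at 12 h and 11 at each later time (7 at 24 h and 6 at 48 h with windows of 500 bp). Of the 22, 6 were kept throughout, at the 54.3rd percentile of fold-matched random lists. CDK6 (16.5) and E2F3 (14.2) were kept, and CCND2 (14.3) and CCNE1 (12.2) were missing at 96 h. The CCND2 DMSO peak was still overlapped by a GLTSCR1 peak in all 4 later lists. Its absence therefore applies to the gene-end window and not to the whole DMSO peak. The fusion was at 12, 11, 6 (10 with windows of 3 kb) and 12 of these genes, among them the CDK inhibitor genes CDKN1C (7.31) and CDKN1B (5.32) at every time.

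Immediate early genes had GLTSCR1 at 14 of 19 in DMSO, 14 at 12 h, 7 at 24 h, 5 at 48 h (10 with windows of 3 kb) and 11 at 96 h. Of the 14 bound in DMSO, 4 were kept throughout, at the 18.9th percentile of fold-matched random lists. JUND, KLF2 (21.0) and KLF6 (11.1) were called at every time, and FOS (27.6) was missing at 48 h. The FOS DMSO peak was still overlapped by a GLTSCR1 peak in all 4 later lists. Its absence therefore applies to the gene-end window and not to the whole DMSO peak. The fusion was at 12, 10, 13 and 12, with FOSL1 (7.47), EGR2 (6.43), KLF4 (6.31) and KLF6 (6.12) at every time. FGF and WNT pathway genes had GLTSCR1 at 20 of 32 in DMSO and 18, 17, 14 and 12 later, and the fusion at 23, 23, 21 and 23. FGF8 kept both proteins, with GLTSCR1 folds from 10.2 to 25.2, as did TCF7L2 (12.1 for GLTSCR1 and 13.0 for the fusion in DMSO). FZD2 and SPRED1 lacked GLTSCR1 at 48 h, WNT7B (fusion 9.22) had no GLTSCR1 peak in DMSO and 1 at every later time, and FZD8 kept both. Of the 23 fusion-bound genes 18 were kept throughout, at the 99.2nd percentile of fold-matched random lists.

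For GBAF and shared BAF subunits GLTSCR1 was at 11 of 14 genes in DMSO and at 11, 4, 3 and 5 at 12, 24, 48 and 96 h. With windows of 500 bp it was at 7 at 12 h and 2 at 24 h. Anywhere in the gene span it was at 6 at 48 h and 8 at 96 h. BICRAL (14.5), ACTB (14.0) and SS18 (6.99) were called at every time, and BCL7A (8.82) in DMSO and at 24 h. The BCL7A DMSO peak was overlapped by a GLTSCR1 peak in 2 of the later lists. The fusion was at 6, 3, 3 and 4 of them; SS18L1 had it in DMSO alone. For other BAF and PBAF subunits GLTSCR1 was at 9, 7, 5, 4 and 4 of 14, with ARID1A (16.6), SMARCE1 (13.6) and ARID2 (7.97) kept. ARID1B (11.3) was last called at its ends at 24 h. Its DMSO peak was still overlapped by a GLTSCR1 peak in all 4 later lists. The absence at 48 and 96 h therefore applies to the gene-end window and not to the whole DMSO peak. The fusion was at 5, 5, 3 and 3, with SMARCD2 (5.04) the highest. Polycomb subunit genes had GLTSCR1 at 20, 20, 13, 12 and 16 of 28 and the fusion at 15, 15, 9 and 14. BCOR (23.2), EZH2 (16.0) and CBX2 (13.9) kept GLTSCR1 at every time, and CBX8 and RYBP kept the fusion. For genes kept at every time none of these 3 lists exceeded the 90th percentile of fold-matched random lists; by time, the Polycomb genes that kept GLTSCR1 lay at the 96.4th at 12 h (19 of 20) and the 98.1st at 96 h (16 of 20).

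BRD9, the target of WA-68 (chromosome 5, 863741 to 892801), had a GLTSCR1 peak in DMSO alone (fold 4.41) and a fusion peak in all 4 lists (2.81 in DMSO, 4.80 at 48 h). BICRA, the gene of GLTSCR1, had a GLTSCR1 peak at 12 h alone (5.21) and no fusion peak. SS18 had GLTSCR1 at all 5 times and the fusion in DMSO and at 12 h (5.90 and 4.50). The 8 SSX genes of the table, SSX1, SSX2, SSX2B, SSX3, SSX4, SSX4B, SSX5 and SSX7, had 0 calls in the 9 lists. Near-identical copies among them can lose reads to mapping filters, whose settings are not given in the sources used here.

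Mesenchymal and matrix genes included DCN and LUM, neighbouring genes of small proteoglycans on chromosome 12, which had GLTSCR1 folds of 33.0 and 24.4 in DMSO and were called at every time. The fusion was called at DCN in all 4 lists (5.14 in DMSO, 4.75 at 48 h) and at LUM in DMSO and at 12 h (5.30 and 6.46). The LUM region at 91098556 to 91135250, whose coverage was looked up after its values were seen, stayed at least 94.2% covered by later GLTSCR1 peaks, while fusion peaks covered 30.9% of it in DMSO, 14.9% at 12 h, 1.84% at 24 h and 6.25% at 48 h. GLTSCR1 was at 13 genes of the 22 in DMSO and 7, 7, 9 and 7 later, with VIM (15.3) and COL6A1 (10.4) kept and SNAI1 (5.21) and COL5A1 (4.18) called in DMSO alone. The 7 of 13 kept at 12 h lay at the 0.65th percentile of fold-matched random lists, and the 6 kept throughout at the 70.4th. The fusion was at 11, 10, 8 and 8, with SNAI1 (7.34) and COL5A1 (5.81) kept and COL1A1 (7.29) and CDH11 (6.36) called in DMSO and at 12 h alone. The CDH11 DMSO peak was still overlapped by a fusion peak in all 3 later lists. The later absence therefore applies to the gene-end window and not to the whole DMSO peak. Epithelial genes had GLTSCR1 at 3, 2, 1, 1 and 1 of 18 and the fusion at 4, 1, 1 and 2. Among random lists the GLTSCR1 shares lay at the 9.1st, 6.9th, 14.4th, 24.9th and 13.3rd percentile. The fusion shares lay at the 63.3rd in DMSO and the 7.6th, 11.3rd and 22.5th later. MUC1 (13.2) kept GLTSCR1, TJP1 and OVOL1 had it in DMSO alone, and KRT19 had a fusion peak in DMSO alone and ESRP1 in DMSO and at 48 h. Of 24 blood and liver genes, GLTSCR1 was at 2 in DMSO and at 12 h (APOA1 and TF) and at 0 afterwards, and the fusion at 1, 1, 2 and 2, with HBA1 in all 4 lists.

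**Figure D4:**
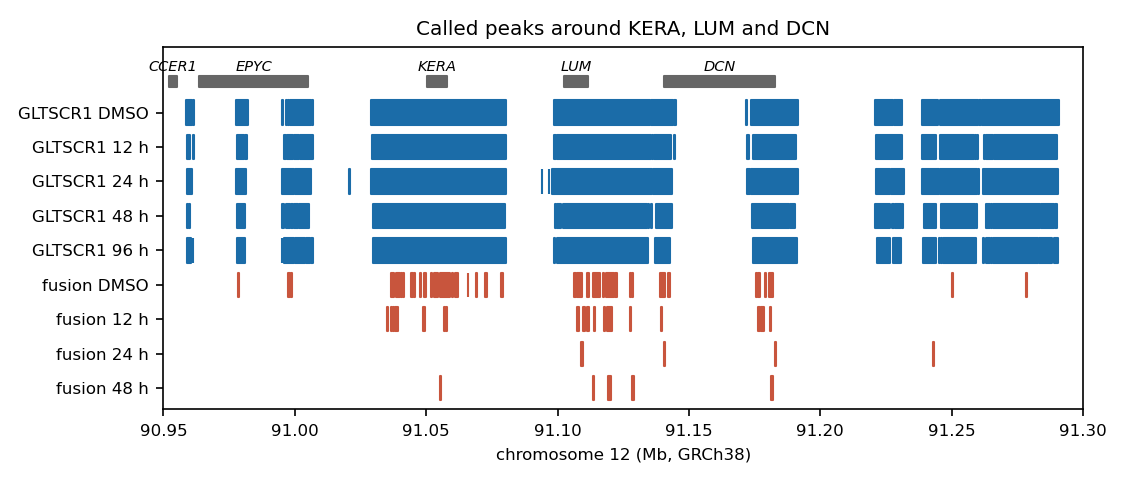
Map of called peaks on chromosome 12 around KERA, LUM and DCN (GRCh38, Mb); grey bars are gene spans and each coloured row is 1 peak list. GLTSCR1 peaks keep nearly the same extent at all 5 times, and fusion peaks over the LUM region cover 30.9% of it in DMSO and 1.84% at 24 h.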

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

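In this part, the test of an excess of gene-end calls in the DMSO library alone and the matching on width were chosen only after the results were seen.

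GLTSCR1 peaks at gene ends moved apart from other GLTSCR1 peaks in opposite directions at different times: at like DMSO fold they were kept 4.89 points more often at 12 h (1.62 with windows of 3 kb), with differences of −19.9 points at 24 h, −26.3 at 48 h and −21.1 at 96 h. The change of direction between times was not tested, since each time has 1 library. Weaker or narrower DMSO peaks at gene ends would remove the difference once both are matched, but in peaks called at every later time it was −16.5 points (−17.6 to −15.5), and with lists of equal length it was −18.6 (−19.9 to −17.3), which argues against shorter lists as the whole cause. An excess of gene-end calls in the DMSO library alone is argued against by the list at 12 h, where 32.8% of peaks lay at gene ends against an upper bound of 20.4% at the later times. WA-68 itself, time in culture, and a difference between library preparations, for which the labels give no batch, stay open and were not tested. The same holds for unspecific recovery of gene ends in both the DMSO and the 12 h library.

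The proteins went opposite ways in 2 comparisons, neither of which was tested for the difference between them. At 12 h the gene-end difference was 4.89 points for GLTSCR1 and −11.9 for the fusion, against 1.62 and −10.1 with windows of 3 kb, and the fusion value was −5.69 with summits within 250 bp. At 24 h, peaks with the other protein differed from peaks without it by 15.4 points for GLTSCR1 and −1.59 for the fusion; the fusion value was 4.92 with summits within 250 bp, so its sign depended on how overlap was defined, and the GLTSCR1 value was 8.77 with such summits. With width matched too the values were 9.54 for GLTSCR1 and −7.78 for the fusion.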

How the results depend on the processing

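Matching on fold and width, a peak anywhere in the gene span and leaving out 1 later list at a time were chosen only after the results were seen. No paired analysis was possible because each group holds 1 library, so no replicate could be left out, and the depth of the libraries is unknown from peak lists. Fusion retention at a given time stayed above GLTSCR1 retention except with summits within 250 bp at 12 h, and gene-end differences for peaks called at every later time stayed below 0 for both proteins. The fusion difference with the other protein, 0.499, took either sign. The GLTSCR1 share with the fusion, higher at 12 h than at 24 h, was lower at 12 h with lists of equal length and with summits within 250 bp. For main results, all values that left their counting interval and counts that moved by over 1.5 times follow; for secondary values, those that moved by over 1.5 times, changes of sign included. In each case the cause was not tested.

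Differences are in points, for peaks called at every later time unless a time is given. At 50% of the shorter peak, GLTSCR1 retention was 52.2% (12 h), 44.1% (24 h), 40.0% (48 h), 45.1% (96 h), fusion retention 64.9% (12 h), 58.1% (24 h), 61.5% (48 h), GLTSCR1 peaks with the fusion 55.9% (DMSO), 51.8% (12 h), 50.6% (24 h), 63.5% (48 h), the GLTSCR1 gene-end difference −15.3, the GLTSCR1 difference with the other protein 14.8, the fusion gene-end difference −4.38, the fusion difference with the other protein 5.28. With summits within 250 bp, GLTSCR1 retention was 39.4% (12 h), 32.4% (24 h), 30.4% (48 h), 33.7% (96 h), fusion retention 35.9% (12 h), 33.9% (24 h), 35.5% (48 h), GLTSCR1 peaks with the fusion 22.5% (DMSO), 22.4% (12 h), 22.5% (24 h), 26.6% (48 h), the GLTSCR1 gene-end difference −9.68, the GLTSCR1 difference with the other protein 5.57, the fusion gene-end difference −3.59, the fusion difference with the other protein 3.75. At −log10 q of at least 5 in every list, GLTSCR1 retention was 54.7% (12 h), 45.7% (24 h), 40.7% (48 h), 46.3% (96 h), fusion retention 65.5% (24 h), 69.7% (48 h), GLTSCR1 peaks with the fusion 54.8% (DMSO), 50.2% (12 h), 48.8% (24 h), 61.8% (48 h), the GLTSCR1 difference with the other protein 16.5. With that limit in the reference list alone, GLTSCR1 retention was 60.5% (12 h), 51.7% (24 h), 47.0% (48 h), 52.6% (96 h), fusion retention 78.4% (12 h), 71.6% (24 h), 75.4% (48 h), GLTSCR1 peaks with the fusion 52.7% (24 h), 65.2% (48 h), the GLTSCR1 gene-end difference −18.9, the GLTSCR1 difference with the other protein 19.5. With lists of equal length, GLTSCR1 retention was 59.2% (12 h), 51.1% (24 h), 49.95% (48 h), 51.6% (96 h), fusion retention 68.6% (12 h), 67.2% (48 h), GLTSCR1 peaks with the fusion 47.7% (DMSO), 42.5% (12 h), 43.8% (24 h), 56.3% (48 h), the GLTSCR1 gene-end difference −18.6. With peaks merged within 500 bp, GLTSCR1 retention was 59.1% (12 h), 50.04% (24 h), 45.5% (48 h), 51.3% (96 h), fusion retention 70.8% (12 h), GLTSCR1 peaks with the fusion 58.3% (DMSO), 54.4% (12 h), 52.2% (24 h), 64.5% (48 h), the GLTSCR1 gene-end difference −19.0, the GLTSCR1 difference with the other protein 19.6, the fusion difference with the other protein 2.30. With width matched too, the GLTSCR1 difference with the other protein was 13.2 and the fusion difference with the other protein −7.49. Of the same fusion difference by time, 12 h went from −4.36 to 2.75 with summits within 250 bp, −1.42 at 50% of the shorter peak, −1.99 with peaks merged and −10.3 with width matched. The value at 24 h went from −1.59 to 4.92 with such summits, 1.30 at 50%, −2.95 with lists of equal length, −0.359 with peaks merged and −7.78 with width matched, and that at 48 h from −0.839 to 5.89, 2.82, 1.402 (merged) and −7.00 (width). The GLTSCR1 gene-end difference at 12 h went from 4.89 to 1.62 with windows of 3 kb and at 24 h from −19.9 to −12.8 with summits within 250 bp. That of the fusion went from −11.9 to −5.69 with such summits at 12 h and from −3.95 to −1.85 with windows of 3 kb at 24 h. The GLTSCR1 difference with the other protein went, with such summits, from 1.35 to 5.17 at 12 h, 15.4 to 8.77 at 24 h, 27.2 to 11.8 at 48 h and 22.3 to 10.2 at 96 h, and with width matched to −4.82 at 12 h and 9.54 at 24 h. Without the 12 h list, 5498 fusion DMSO peaks were called at no later time.

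At −log10 q of at least 5 in every list, list counts became 5 cell cycle (GLTSCR1 48 h), 1 blood and liver (GLTSCR1 DMSO), 2 BAF and PBAF (fusion 12 h), 1 BAF and PBAF (fusion 24 h), 5 mesenchymal (fusion 24 h), 1 epithelial (fusion DMSO), 1 blood and liver (fusion 24 h). With lists of equal length, list counts became 1 blood and liver (GLTSCR1 DMSO). Anywhere in the gene span, bound genes were 4751 (GLTSCR1 24 h), 3653 (GLTSCR1 48 h), 4690 (GLTSCR1 96 h), 2325 (kept throughout for GLTSCR1). Anywhere in the gene span, list counts became 6 GBAF (GLTSCR1 48 h), 8 GBAF (GLTSCR1 96 h), 7 BAF and PBAF (GLTSCR1 48 h), 11 mesenchymal (GLTSCR1 96 h), 2 epithelial (GLTSCR1 24 h), 2 epithelial (GLTSCR1 48 h), 2 epithelial (GLTSCR1 96 h), 6 GBAF (fusion 12 h), 5 BAF and PBAF (fusion 24 h), 5 BAF and PBAF (fusion 48 h), 10 cell cycle (fusion 24 h), 2 epithelial (fusion 12 h), 2 epithelial (fusion 24 h). With windows of 3 kb, list counts became 24 developmental factors (GLTSCR1 12 h), 27 developmental factors (GLTSCR1 48 h), 10 immediate early (GLTSCR1 48 h), 2 epithelial (GLTSCR1 96 h), 10 cell cycle (fusion 24 h), 2 epithelial (fusion 12 h), 2 epithelial (fusion 24 h), 4 epithelial (fusion 48 h), 2 blood and liver (fusion DMSO). With windows of 500 bp, list counts became 7 GBAF (GLTSCR1 12 h), 2 GBAF (GLTSCR1 24 h), 3 BAF and PBAF (GLTSCR1 24 h), 7 cell cycle (GLTSCR1 24 h), 6 cell cycle (GLTSCR1 48 h), 2 epithelial (fusion DMSO), 1 epithelial (fusion 48 h). The other 641 values of main results stayed within their interval or within 1.5 times, as did 129 secondary values, while another 50 secondary values did not, and 3 went from an interval off 0 to the opposite sign. Windows of 3 kb moved the gene-end share of all 9 lists, over 1.5 times only for GLTSCR1 at 48 h, from 17.0% to 25.8%.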

Other observations

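In this part, the test of lower sensitivity in the 24 h fusion library, the test of an even loss of sensitivity in the GLTSCR1 libraries, the finer matching on fold and the demand that a gap between overlaps exceed counting error were chosen only after the result was seen, and the histone genes and wide regions were named after their values were seen.

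Of 55 histone genes on chromosome 6, GLTSCR1 was at the ends of 50 in DMSO and 49, 50, 48 and 49 at 12, 24, 48 and 96 h, while the fusion was at 40 in DMSO and 32, 24 and 28 at 12, 24 and 48 h. Many of them share regions: a stretch of 34.8 kb from H2BC13 to H2BC15 was 1 GLTSCR1 region in DMSO and stayed at least 92.0% covered by GLTSCR1, and fusion peaks covered 18.4% of it in DMSO and 10.7%, 13.2% and 7.58% later. Ribosomal DNA contigs, left out of the comparisons, differed between antibodies: the contig GL000220v1 held 47 fusion entries in DMSO and 40, 54 and 45 later, against 5 GLTSCR1 entries in DMSO and at most 1 later.

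In DMSO, 227 GLTSCR1 regions were wider than 5 kb. The widest covered ZIC1 and ZIC4 on chromosome 3 (147346960 to 147428632), and others lay in DNM3, at KERA (chromosome 12, 91029135 to 91080443) and on chromosome 8 at 78002378 to 78036107, 480.2 kb from the nearest gene, PKIA. GLTSCR1 still covered 76.7% of their length at 12 h, 77.4% at 24 h, 74.0% at 48 h and 72.4% at 96 h. Fusion peaks covered 56.6% in DMSO, 45.4% at 12 h, 35.7% at 24 h and 40.1% at 48 h; over ZIC1 and ZIC4 the fusion covered 40.9%, 17.4%, 9.25% and 10.3%. The 1172 wide fusion regions, among them those at NKX6-2, PRDM16, MNX1 and IRX4, stayed 94.0%, 87.3% and 90.8% covered by the fusion, while GLTSCR1 covered 33.0% of their length in DMSO and 21.8%, 23.5%, 24.2% and 27.1% later. Each protein thus covered less of the wide regions of the other after DMSO. For GLTSCR1 this went with shorter lists, which covered 16.8 Mb in DMSO and 11.1, 10.5, 8.55 and 10.3 Mb later. It touched 1051 of the wide fusion regions in DMSO and 979, 1002, 1051 and 1071 later. The fusion lists covered 33.9 Mb in DMSO and 36.4, 30.3 and 33.4 Mb later, and touched 218 of the wide GLTSCR1 regions and then 201, 188 and 196.

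The lower fusion coverage of wide GLTSCR1 regions at 24 h than in DMSO was weighed against technical explanations. Suppose carry-over of GLTSCR1 chromatin or reads, following summit fold, were the sole source of fusion DMSO calls at GLTSCR1 summits. Narrower peaks of like fold would then hold a fusion peak as often as wide ones. Summits in wide regions instead lay in a fusion DMSO peak 40.0 points more often (33.8 to 46.2). With 50 groups of fold in place of deciles the difference was 33.0 points. That argues against carry-over by fold as the sole source of these calls. Fusion binding that favours wide regions would give this difference with or without added carry-over, so the test cannot decide whether some was added. Carry-over that grows with the width of a region may also contribute. Fusion DMSO peaks in wide GLTSCR1 regions were called at 24 h less often than other fusion peaks of like fold and width. The difference was −21.4 points (−25.0 to −17.9) over 614 peaks, which argues against an even loss of sensitivity at 24 h. These peaks lie in 218 wide regions and are not independent, so the interval is too narrow. A loss of the fusion from these regions under WA-68 stays an untested hypothesis, since each time has 1 library.

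The GLTSCR1 lists were shorter at every WA-68 time than in DMSO, and lower caller sensitivity alone in the treated libraries could give shorter lists. If that loss were even over peaks of like fold, gene ends and other places would be kept alike. In lists of equal length gene-end peaks were called at every later time less often, by −18.6 points (−19.9 to −17.3). That argues against an even loss as the whole cause, but it is the value already given above for gene ends and no separate evidence. In such lists the DMSO list overlapped the treated lists by 57.0% on average (54.6% to 62.5%), against 60.8% on average among the treated lists (57.8% to 64.5%). The DMSO mean lies under the lowest of these treated overlaps, which was the sign written down beforehand for a change beyond sensitivity, but by less than counting error, whose lower bound is 56.9%. A loss of sensitivity that differs between kinds of sites and a change in binding under WA-68 therefore cannot be told apart here, and read depths were not analysed here.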
